A study of Mus musculus with 24 samples.

How the data were processed

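RNA was taken from 24 tumours of Lewis Lung Cancer cells grown in wild-type mice, 8 per group, and libraries were made with a stranded poly(A) ligation kit, per the labels' protocols. Per the labels' protocols, the dual group received 100 ug of anti-PD-1 by intraperitoneal injection on days 7, 10 and 14 and 50 ug of poly I:C into the tumour on days 11 and 15. The triple group also received PMX53, taken here as the C5aR1 blocker that the group labels name, at 1 mg/kg under the skin each day from day 6. The submitters' processing notes name FastQC 0.11.8, STAR 2.7.9a, featureCounts 1.6.0, edgeR and limma and the mouse genome build GRCm39, with no order or settings.

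The deposited table holds log2 values, and the values themselves identify them as log2 CPM. They fitted, in each tumour, log2 of reads plus 0.5 over a scaled library size, so whole reads were worked back for 100% of values within 0.01 reads. Totals per tumour ran from 14438318 to 17225195 reads in vehicle, 14535983 to 19046105 reads in dual and 15671388 to 19254090 reads in triple tumours. The scaled library size differed from the total by a factor of 0.88 to 1.07. The table lists 18723 genes, of which 2701 had 0 reads in some tumour; the filter that left these genes is not given in the sources used here. No 2 tumours held identical values. Gene IDs, symbols and GRCm39 coordinates were taken from the deposited table. Genes of multigene families, such as the H2, Klra, Ly6 and globin genes, can share reads and their values are less certain.

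Groups were taken from the sample labels. The main test was limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 1 mean per group over all 24 tumours, a variance trend, no robust option, and Benjamini-Hochberg adjustment over all genes, called at an adjusted p under 0.05. The fits with precision weights and median-of-ratios scaling used the recovered reads in limma. The 32 gene lists were fixed before the data were examined and tested with limma's camera with a preset correlation of 0.01, adjusted over lists within each comparison. Beside it stood camera with an estimated correlation, fry, and a two-sided exact permutation test over all 12870 assignments of 8 against 8 tumours of the list score. A list score is the mean over members of each gene's value standardised over the 24 tumours. Principal components used genes at or above the median expression. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

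Genes named in the text followed a rule fixed before the data were examined, except those stated to have been chosen after the data were seen. The rule took, for each comparison, the 10 largest increases and the 10 largest decreases among called genes of at least median expression, leaving out predicted and clone-based names and variable segments of antigen receptors. To these it added the 3 members with the smallest p of each called list, and 21 genes given in advance. The alternatives tried were robust or untrended variance, tumour weights, fits on 2 groups alone, a filter at the 25th percentile of expression, median centring, quantile normalization, an exact Wilcoxon test, stricter thresholds, the skeletal muscle score as a covariate, and leaving out each tumour in turn. Added after seeing the data were precision weights, median-of-ratios scaling, the adipocyte score as a covariate, and fits without triple tumours rich in muscle reads.

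The test was checked on simulated data of 18723 genes with 200 changed. Genes were drawn independently, with 1 spread per gene, averaged over the 3 groups and used for every comparison. At 1.5-fold, 2-fold and 4-fold the test recovered 46.3%, 76.1% and 87.9% of genes changed in dual against vehicle. The values were 50.7%, 89.6% and 97.0% for triple against vehicle and 49.3%, 74.6% and 90.9% for triple against dual. Of the simulated calls, 3.45%, 8.14% and 4.03% were false in the same order. The simulations leave out the wider spread of the triple tumours and the correlation between genes, so rates in the real comparisons may differ. The labels do not state library batches or dates. A separate mouse number for each tumour is the only sign in the labels that tumours came from separate animals.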

Results

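Tumours of the Lewis Lung Cancer line, a mouse lung adenocarcinoma line, were profiled by bulk RNA-seq after growth in wild-type mice. The 24 tumours fell into 3 groups of 8. The vehicle group received vehicle. The dual group received poly I:C, a synthetic double-stranded RNA that stimulates nucleic-acid sensors, into the tumour, together with an antibody against the checkpoint receptor PD-1. The triple group received the same 2 agents and blockade of C5aR1, the receptor for the complement fragment C5a, with PMX53. The comparisons asked what the dual treatment changed, what the triple treatment changed, and what the addition of C5aR1 blockade changed. Reads assigned to genes ranged from 14438318 to 19254090 per tumour over 18723 genes. Tumours are named by a group letter (C for vehicle, D for dual, T for triple), the mouse number and the library number, as in their titles. Each mouse number occurred once, so tumours were not paired between groups. The library numbers in the sample titles ran in blocks that coincided with the groups, so a library batch and the group cannot be told apart.

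On a principal component analysis of 9362 genes, the leading component held 52.4% of the variance and the next 23.1%. The vehicle tumours lay together, the dual tumours lay apart from them on both components, and the triple tumours were spread widely. Triple tumour T_352_S48 lay farthest out on the leading component at 73.1, and triple tumour T_331_S44 lay at -16.5. The triple tumours also held a higher share of skeletal muscle and adipocyte marker reads, whose origin was not tested. Skeletal muscle markers took 0.0409% ± 0.014 (SD, n = 8) of the reads in vehicle, 0.0615% ± 0.027 (SD, n = 8) in dual and 0.148% ± 0.089 (SD, n = 8) in triple tumours. The triple share exceeded the dual share with p = 0.0193 in a two-sided exact permutation test. Adipocyte markers took 0.0126% ± 0.0035 (SD, n = 8) of the reads in dual and 0.029% ± 0.019 (SD, n = 8) in triple tumours, with p = 0.0112 in the same exact permutation test.

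**Figure D1:**
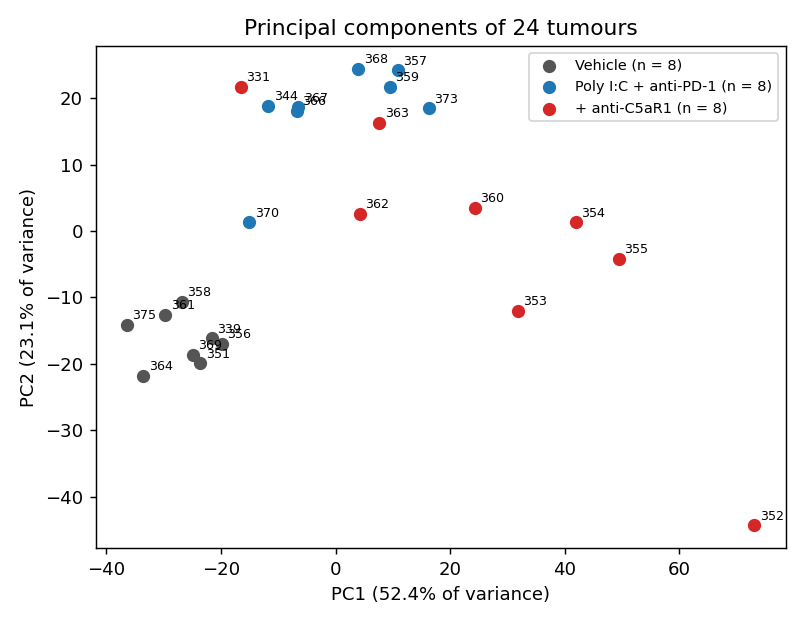
Scores of the 24 tumours on the leading pair of principal components, which hold 52.4% (horizontal axis) and 23.1% (vertical axis) of the variance. Each point is a tumour, coloured by group and marked with its mouse number; triple tumour T_352_S48 lies apart from the rest.

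Dual treatment was set against vehicle to ask what poly I:C with PD-1 blockade changed. Neutrophil markers rose most, with 27 of 29 measured members higher, 27 adjusted over the list alone, and a median log2 fold change of 3.10. S100a8, a subunit of calprotectin, rose by 4.41 ± 0.40 (SE, n = 8 per group; adjusted p = 8.13e-08; 8 of 8 dual tumours above the vehicle median), Retnlg by 5.12, the collagenase Mmp8 by 3.59, and Ly6g, a surface marker of mouse neutrophils, by 3.69. Inflammatory cytokines and NF-kappaB targets rose in 27 of 37 members, and in 30 adjusted over the list alone (median 1.10). Among them were the prostaglandin synthase Ptgs2 (log2 fold change 3.10) and the neutrophil chemoattractant Cxcl5 (2.19). The related chemokines Cxcl3 and Cxcl2 rose by 4.47 and 3.98, and their receptor Cxcr2 by 3.32. Type I interferon response genes rose in 35 of 46 members, and in 40 adjusted over the list alone (median 1.06), including Rsad2 (2.23), Bst2 (1.44) and Rtp4 (1.52). Their camera adjusted p was 1.78e-14, that of neutrophil markers 1.44e-22 and that of inflammatory genes 5.43e-13. With an estimated correlation the adjusted p was 0.268 for neutrophil markers, 0.411 for inflammatory genes and 0.587 for type I interferon genes.

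Antigen-presentation genes moved apart. MHC class II genes fell in 9 of 12 members, and in 10 adjusted over the list alone (median -1.57; camera adjusted p = 9.06e-07; adjusted p = 0.448 with an estimated correlation). The class II transactivator Ciita fell by 2.80 on the log2 scale, H2-Ab1 by 1.77 and the peptide-loading gene H2-DMb1 by 1.89. Dendritic cell markers fell in 8 and rose in 1 of 26 members, with 1 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.75 with an estimated correlation), with Cd209a at a log2 fold change of -3.82 and Clec9a, a marker of cross-presenting dendritic cells, at a log2 fold change of -2.01. MHC class I genes rose in 9 of 23 members, and in 11 adjusted over the list alone (median 0.27; camera adjusted p = 0.00387; adjusted p = 0.75 with an estimated correlation), with B2m at 0.61. Cd274, which encodes the PD-1 ligand PD-L1, rose by 1.94 ± 0.26 (SE, n = 8 per group; adjusted p = 1.02e-05; 8 of 8 dual tumours above the vehicle median), and Pdcd1lg2, the other PD-1 ligand gene, by 1.46. Of 27 T cell markers, 0 rose and 0 fell in limma's test. At an unadjusted p under 0.05 the number was 0. The log2 fold change of Cd8a was 0.37 ± 0.34 (SE; adjusted p = 0.426) and that of Ifng 0.18 ± 0.48 (SE; adjusted p = 0.803). The cytotoxic genes Gzmb and Prf1 rose by 1.47 and 1.42, and cytotoxic effector genes as a list rose in 5 of 21 members, and in 5 adjusted over the list alone (camera adjusted p = 0.0301; adjusted p = 0.75 with an estimated correlation). Without vehicle tumour C_358_S26, C_364_S28 or C_375_S31 the adjusted p of the cytotoxic list was 0.0807, 0.0653 and 0.0551, and with the muscle score as a covariate it was 0.299.

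Hypoxia and glycolysis genes rose in 20 and fell in 4 of 34 table rows, in which 1 of its 33 symbols stands for 2 gene IDs, with 22 higher and 5 lower adjusted over the list alone (camera adjusted p = 7.6e-06; adjusted p = 0.587 with an estimated correlation), among them Eno1 (0.86) and Pkm (0.61). Immediate early and heat shock genes rose in 17 of 23 with 1 lower, and in 18 with 1 lower adjusted over the list alone (camera adjusted p = 9.06e-07; adjusted p = 0.411 with an estimated correlation). Mitochondrially encoded genes fell in 6 of 11, and in 8 adjusted over the list alone (median -0.78; camera adjusted p = 0.000354; adjusted p = 0.499 with an estimated correlation). The matrix proteoglycan genes Lum and Aspn fell by 2.33 and 2.85 on the log2 scale, and Dpt by 2.16, while the fibroblast and extracellular matrix list was not called, with 6 higher and 8 lower of 30, 8 and 8 adjusted over the list alone (median 0.16; camera adjusted p = 0.758). Skeletal muscle markers rose in 2 of 20, and in 0 adjusted over the list alone (median 0.53; camera adjusted p = 0.0303; adjusted p = 0.755 with an estimated correlation). Without vehicle tumour C_375_S31 or dual tumour D_359_S39 or D_366_S34 the adjusted p of the muscle list was 0.118, 0.0717 and 0.062. The cystine transporter gene Slc7a11 rose by 3.38. In all, limma called 2803 genes higher and 2957 lower at an adjusted p under 0.05, 738 and 727 of them by at least 2-fold. With tumour weights the numbers were 4436 and 4775.

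Triple treatment against vehicle asked what all 3 agents changed together. Neutrophil markers were again far higher, with 28 of 29 members up, 28 adjusted over the list alone (median log2 fold change 3.23; camera adjusted p = 4.17e-18; adjusted p = 0.345 with an estimated correlation). Cytotoxic effector genes were higher in 18 of 21 members, and in 19 adjusted over the list alone (median 2.06), T cell markers in 22 of 27 with 1 lower, and in 22 with 1 lower adjusted over the list alone (median 1.19), and natural killer cell markers in 13 of 16, and in 14 adjusted over the list alone (median 1.54). Gzmb, a granule protease of cytotoxic lymphocytes, rose by 3.19 ± 0.37 (SE, n = 8 per group; adjusted p = 8.29e-07; 8 of 8 triple tumours above the vehicle median), Prf1 by 3.02, Gzma by 3.72, Cd8a by 1.82 and Ifng by 2.12. Camera adjusted p was 2.48e-08 for cytotoxic genes, 6.26e-06 for T cell markers and 4.9e-05 for natural killer markers. With an estimated correlation the adjusted p was 0.345, 0.406 and 0.345 for these lists. The T cell list was no longer called with the muscle score as a covariate (adjusted p = 0.159). A further fit left out the 5 triple tumours whose muscle share exceeded that of every other-group tumour, a selection made after the data were seen. In it neither the T cell list (adjusted p = 0.229) nor the natural killer list (adjusted p = 0.083) was called. Those 5 included the triple tumours with the highest T cell scores (1.98, 1.42, 1.40 and 1.24), so this fit also removed part of the T cell rise itself.

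Interferon-gamma response genes rose in 29 of 32 members with 1 lower, and in 30 with 1 lower adjusted over the list alone (median 1.43) and type I interferon response genes in 43 of 46, and in 43 adjusted over the list alone (median 1.36), with Oas3 higher by 2.32 and Irf7 by 2.29. Adjusted p was 0.345 and 0.345 with an estimated correlation, against camera values of 3.95e-10 and 1.83e-15. MHC class I genes rose in 19 of 23, and in 19 adjusted over the list alone (camera adjusted p = 1.12e-06; adjusted p = 0.345 with an estimated correlation), with the peptide transporter gene Tap1 higher by 1.35, while MHC class II genes fell in 9 and rose in 1 of 12, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.000241; adjusted p = 0.345 with an estimated correlation), with H2-Aa at a log2 fold change of -1.92. Macrophage markers rose in 13 and fell in 1 of 24, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00432; adjusted p = 0.54 with an estimated correlation), and Cd68 was higher by 1.67. The macrophage list was no longer called with the muscle score as a covariate (adjusted p = 0.62) or without the same 5 triple tumours (adjusted p = 0.76). Skeletal muscle markers rose in 18 of 20, and in 18 adjusted over the list alone (median 1.69; camera adjusted p = 1.56e-06; adjusted p = 0.345 with an estimated correlation), and the muscle actinin gene Actn3 by 2.16. Adipocyte markers rose in 6 of 11, and in 6 adjusted over the list alone (camera adjusted p = 0.00597; adjusted p = 0.415 with an estimated correlation), and the lipase gene Lpl by 2.51; the adipocyte call was lost with the same covariate (adjusted p = 0.954) and without those 5 tumours (adjusted p = 0.429). Mitochondrially encoded genes fell in 8 of 11, and in 8 adjusted over the list alone (camera adjusted p = 0.000853; adjusted p = 0.345 with an estimated correlation).

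In all, 4297 genes were called higher and 4263 lower against vehicle, against 3692 and 5372 with quantile normalization and 3637 and 4764 with median centring. A fit with the muscle score as a covariate called 1893 and 1862.

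**Figure D2:**
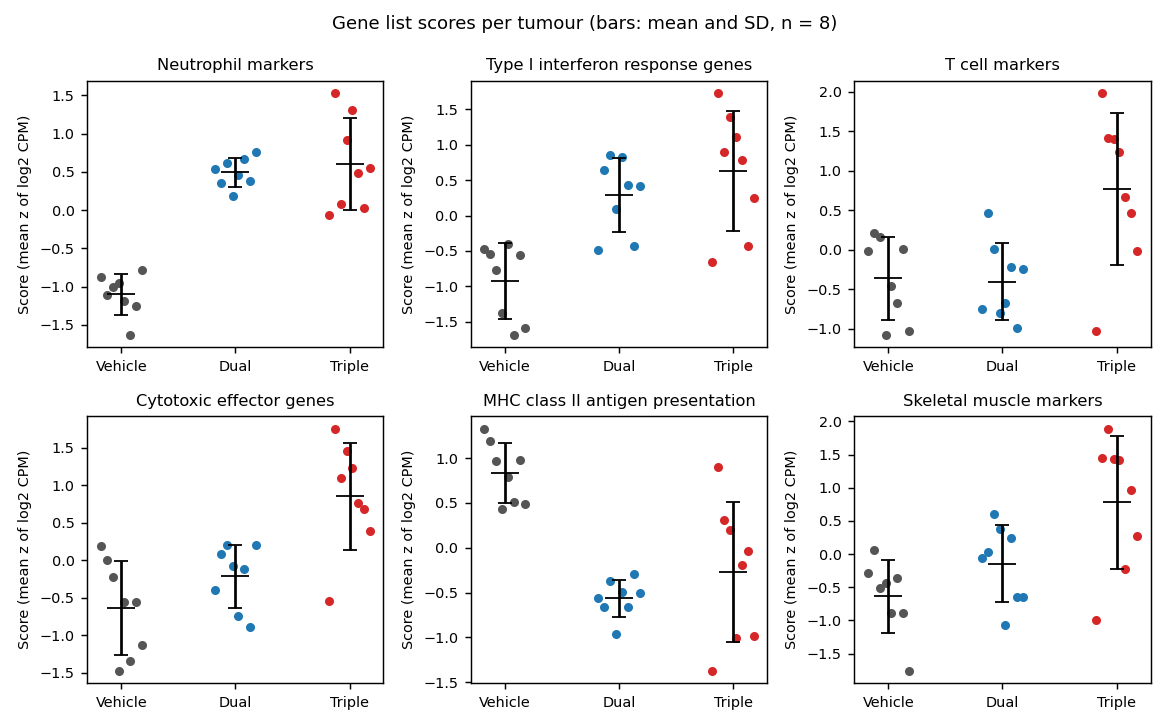
Scores of 6 gene lists per tumour, as the mean z value of the members' log2 CPM (vertical axis), for the vehicle, dual and triple groups of 8 tumours (horizontal axis). Points are tumours and bars give the mean and SD; neutrophil scores were higher in every treated tumour than in any vehicle tumour, and T cell scores of the triple tumours spanned the widest range.

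Triple against dual asked what C5aR1 blockade added. T cell markers rose in 21 of 27 members, and in 23 adjusted over the list alone (median log2 fold change 1.17), cytotoxic effector genes in 14 of 21, and in 17 adjusted over the list alone (median 1.43), and natural killer cell markers in 12 of 16 with 1 lower, and in 14 with 2 lower adjusted over the list alone (median 1.49). Cd8a rose by 1.44 ± 0.34 (SE, n = 8 per group; adjusted p = 0.00842; 7 of 8 triple tumours above the dual median), Cd8b1 by 1.73, Gzmb by 1.72, Prf1 by 1.60 and Ifng by 1.94. Each SE rests on 1 spread per gene shared by all 24 tumours. The T cell signalling kinase gene Zap70 rose by 1.60 and Tbx21, which encodes the transcription factor T-bet, by 1.58. Skeletal muscle markers took 0.148% of the reads in triple and 0.0615% in dual tumours. Camera adjusted p was 2.39e-09, 1.1e-07 and 7.59e-05 for these lists. With an estimated correlation the adjusted p was 0.624, 0.624 and 0.624. The permutation test of the score per tumour gave an adjusted p of 0.0682, 0.0365 and 0.0682. In a fit with the muscle score as a covariate the median T cell log2 fold change was 0.59 (camera adjusted p = 3.77e-06), that of cytotoxic genes 0.79 (camera adjusted p = 2.26e-05), and that of Cd8a was 0.85 (adjusted p = 0.164). Without the 5 muscle-rich triple tumours the median was 0.28 for T cell markers (camera adjusted p = 0.0215) and 0.54 for cytotoxic genes (camera adjusted p = 0.00256). It was 0.32 for natural killer markers, which were no longer called (camera adjusted p = 0.294). That fit left out the highest T cell scores (1.98 to 1.24) and kept the lowest, -1.03 in T_331_S44. A smaller T cell median would follow whatever part muscle played. The log2 fold change of Cd4 was -0.17 ± 0.32 (SE; adjusted p = 0.726) and that of Foxp3, the regulatory T cell factor, 0.07 ± 0.35 (SE; adjusted p = 0.895). The regulatory T cell list was not called (median -0.18; camera adjusted p = 0.449), but camera called it lower with the covariate (median -0.49; adjusted p = 0.0139) and without the 5 tumours (median -0.50; adjusted p = 0.000528).

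These calls moved with the skeletal muscle score of the tumours. With the muscle score as a covariate, 6 genes were called higher and 3 lower, against 2140 and 1867 without it. At an unadjusted p under 0.05 the covariate fit held 3176 genes. The fold changes kept their sign for 4007 of the 4007 genes called without the covariate, and the median size of those fold changes went from 0.55 to 0.39. Of the 9 genes called with the covariate, 8 were also called without it. Of the 25 genes that the naming rule gave for the text on this comparison and limma called, 0 were called with the covariate, with a lowest adjusted p of 0.0848. The fold changes given for this comparison are those without the covariate unless stated.

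Interferon-gamma response genes rose in 18 of 32 members, and in 20 adjusted over the list alone (camera adjusted p = 1.81e-07; adjusted p = 0.624 with an estimated correlation), with Irf8 higher by 1.05 and Il18bp by 1.03. Macrophage markers rose in 14 of 24, and in 18 adjusted over the list alone (camera adjusted p = 3.58e-07; adjusted p = 0.624 with an estimated correlation), with Csf1r, the receptor for the macrophage growth factor, higher by 1.16 and Mertk, a receptor for apoptotic cells, by 1.18. Without the 5 muscle-rich triple tumours the macrophage list was not called (median 0.11, adjusted p = 0.25). MHC class I genes rose in 9 of 23, and in 10 adjusted over the list alone (camera adjusted p = 0.000217; adjusted p = 0.624 with an estimated correlation). Lytic cell death genes rose in 9 of 19, and in 9 adjusted over the list alone (camera adjusted p = 0.000313; adjusted p = 0.624 with an estimated correlation), with Casp1 higher by 0.92. With the muscle covariate and without the 5 tumours in turn, the medians went from 0.81 to 0.49 and 0.47 for interferon-gamma genes, from 0.39 to 0.20 and 0.12 for MHC class I genes and from 0.35 to 0.17 and 0.10 for lytic cell death genes, and camera called these lists in both fits. Type I interferon response genes rose in 5 of 46, and in 0 adjusted over the list alone; their camera adjusted p was 0.0181, and the adjusted p was 0.856 with an estimated correlation. With the muscle score as a covariate the type I list was no longer called (median log2 fold change -0.03), and its adjusted p was 0.191, 0.144 and 0.0628 without triple tumours T_352_S48, T_354_S47 and T_355_S43 in turn, and 0.132 and 0.138 without dual tumours D_344_S33 and D_370_S38. The median log2 fold change of neutrophil markers was 0.24 (camera adjusted p = 0.521). Without the 5 muscle-rich triple tumours it was -0.26, and camera called the list lower (adjusted p = 0.0253). Ly6g fell by 1.29 on the log2 scale (adjusted p = 0.0446), a call that leaving out any of 13 single tumours ended.

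Skeletal muscle markers rose in 9 of 20, and in 16 adjusted over the list alone (median 1.09; camera adjusted p = 1.56e-05; adjusted p = 0.624 with an estimated correlation) and skin keratinocyte markers in 3 of 9, and in 5 adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.624 with an estimated correlation), with the epidermal gene Dmkn higher by 2.73. The keratinocyte median went from 1.42 to 2.05 with the muscle covariate (adjusted p = 2.26e-05) and to 2.25 without the 5 muscle-rich tumours (adjusted p = 1.36e-07), where the scores of the 3 triple tumours left, T_331_S44, T_360_S46 and T_363_S41, were -0.76, 2.55 and 0.67. The keratinocyte list was not called in triple against vehicle (camera adjusted p = 0.203) or in dual against vehicle (median -0.43; camera adjusted p = 0.205), but the permutation test of the score per tumour called it lower in dual than in vehicle (adjusted p = 0.00704; mean score -0.53 against 0.02). Among single genes, the chitinase-like gene Chil3 rose by 2.55 and Ly6c2, a monocyte marker, by 1.77, while the chemokine gene Cxcl1 fell by 1.35 on the log2 scale and Hbb-bs, a beta-globin gene, by 1.51.

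Of the 32 gene lists fixed before the data were examined, camera called 18 in dual against vehicle, 25 in triple against vehicle and 16 in triple against dual. With an estimated correlation camera called 0, 0 and 0, with 3, 2 and 0 at an unadjusted p under 0.05. Limma's fry called 9, 23 and 9, and the permutation test of the score per tumour called 13, 22 and 3. In triple against dual those were the cytotoxic, lytic cell death and keratinocyte lists, while the other 13 lists that camera called had an adjusted p of 0.0682 to 0.504 in the permutation test, among them interferon-gamma (0.0682), macrophage (0.0682), MHC class I (0.0867) and complement genes (0.088). Against vehicle 7 lists called by camera in dual (0.0565 to 0.172, with MHC class I at 0.0831, muscle at 0.14 and cytotoxic genes at 0.172) and 3 in triple tumours (0.0571 to 0.113, with macrophage markers at 0.0667) were not called by it.

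Limma called 4007 genes in all between triple and dual. Leaving out triple tumour T_331_S44 gave 6673, leaving out T_352_S48 gave 2471 and leaving out T_353_S45 gave 2424. The exact Wilcoxon test called 789 genes, 433 of them lower. Of the genes called by limma, 53.4% were higher, against 36.7% with median centring, which moved the median of all genes to -0.10, and 42.6% with quantile normalization. The main fit shared 1 spread per gene over all 24 tumours. The SD of the T cell score was 0.96 in triple, 0.49 in dual and 0.53 in vehicle tumours. The shared spread may thus understate the SE for triple against dual. A fit on those 2 groups alone called 1374 genes.

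**Figure D3:**
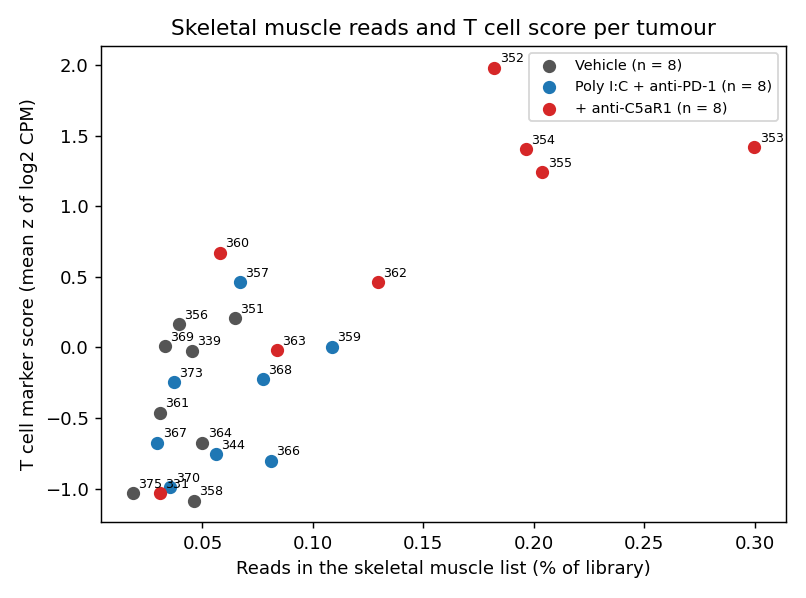
T cell marker score (vertical axis, mean z value of log2 CPM) against the percent of reads in the skeletal muscle list (horizontal axis) for 24 tumours, coloured by group and marked with the mouse number. The highest muscle share of a vehicle or dual tumour was 0.109%, and 5 triple tumours lay above it.

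Genes of the complement pathway were followed across the groups, since the added agent acts on a complement receptor. C5ar1 (ENSMUSG00000049130, chromosome 7, 15980668 to 15993465), in GRCm39 coordinates, had log2 fold changes of 0.78 ± 0.26 (SE; adjusted p = 0.0242) in dual against vehicle, 1.75 ± 0.26 (SE; adjusted p = 1.36e-05) in triple against vehicle and 0.97 ± 0.26 (SE; adjusted p = 0.014) in triple against dual. C3 (ENSMUSG00000024164, chromosome 17, 57510970 to 57535136), the central complement component, changed by 1.38 ± 0.39, 2.76 ± 0.39 and 1.38 ± 0.39 (SE) in the same order, with adjusted p of 0.00842, 7.4e-06 and 0.0176. The receptor gene C3ar1 had 0.42 ± 0.26, 1.49 ± 0.26 and 1.07 ± 0.26 (SE), of which the latter pair passed the threshold. As a list, complement genes rose in 10 and fell in 1 of 36 members, with 18 higher and 2 lower adjusted over the list alone in triple against dual (camera adjusted p = 0.00018; adjusted p = 0.624 with an estimated correlation). Without the 5 muscle-rich triple tumours that call was lost (median 0.68 to 0.13, adjusted p = 0.324). The list was not called in dual against vehicle, with 7 higher and 4 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.408). In triple against vehicle 15 were higher and 3 lower, and 17 and 3 adjusted over the list alone (camera adjusted p = 0.00159; adjusted p = 0.437 with an estimated correlation), a call lost with the muscle covariate (adjusted p = 0.1). With the muscle score as a covariate, the triple against dual values were 0.57 for C5ar1 (adjusted p = 0.241) and 0.67 for C3 (adjusted p = 0.302). C5 itself, encoded by Hc, had between 1 and 30 reads per tumour and was not called in any comparison.

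**Figure D4:**
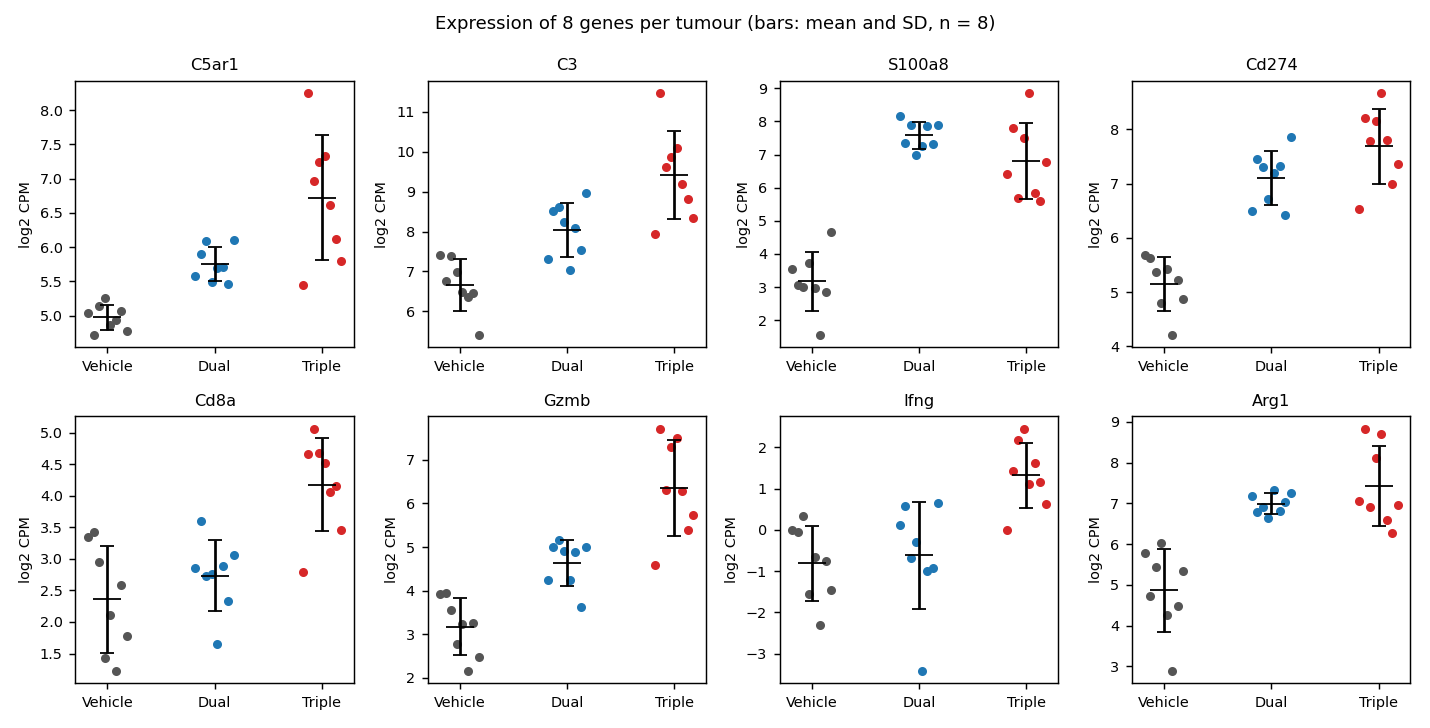
Log2 CPM (vertical axis) of 8 genes per tumour in the vehicle, dual and triple groups of 8 tumours (horizontal axis), with the mean and SD as bars. S100a8 was higher in the treated groups, with log2 fold changes of 4.41 in dual and 3.63 in triple against vehicle.

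The responses to the dual and triple treatments shared the vehicle tumours as controls. Across genes, which are not independent replicates, their log2 fold changes correlated with r = 0.757 and a covariance of 0.457. In 100 simulations of unchanged groups that shared controls, the mean r was 0.486 and the highest r 0.780. The mean simulated covariance was 0.0475 and the highest 0.158, so the observed covariance exceeded the simulated mean by 0.410. With different vehicle tumours for the 2 comparisons, r was 0.647 and 0.662 and the covariance 0.416 and 0.423 in 2 splits. Sharing the vehicle tumours thus accounted for little of the covariance of 0.457. Genes higher in both numbered 1821, against 643.3 for independent lists, and genes lower in both 2101, against 673.3. The numbers for independent lists leave out the shared controls and the simulated values leave out the effects, so neither excess measures a shared effect. The simulations shuffled residuals over all 24 tumours, so those of the widely spread triple tumours could stand as controls. Simulated values can thus differ from those that the vehicle tumours alone would give.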

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

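The tests that weigh explanations of the T cell, neutrophil and lost-call patterns were chosen after the results were seen, while the counts over splits of the tumours were set before those counts were computed.

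Each of the 32 list scores and each of 57 genes that the naming rule fixed in advance gave for the text was examined within each group of 8 tumours for a tumour at an end of the range whose gap to its neighbour, as a share of the range, exceeded Dixon's critical value. This held for 19 of 267 sets of values (7.12%), where chance gives about 1 in 20. In dual tumour D_366_S34 the gap was 0.547 for the score of alternatively activated or immunosuppressive myeloid genes and 0.531 for Cxcl2, each at the low end. For dual tumour D_367_S35 it was 0.597 for Ifng, at the low end. Dual tumour D_370_S38 had a gap of 0.532 for Ciita, at the high end. In dual tumour D_373_S40 the gap was 0.629 for the score of complement components, receptors and regulators and 0.531 for the score of endothelial and pericyte markers, each at the high end. For triple tumour T_331_S44 it was 0.609 for the score of mast cell and eosinophil markers, at the low end. Triple tumour T_352_S48 had a gap of 0.530 for the score of mitochondrially encoded genes, at the low end, and 0.660 for Aspn, at the high end. In vehicle tumour C_339_S25 the gap was 0.546 for the score of mitochondrially encoded genes, at the high end. For vehicle tumour C_361_S32 it was 0.622 for Hc, at the low end. Vehicle tumour C_364_S28 had a gap of 0.573 for the score of inflammatory cytokines and NF-kappaB targets, 0.565 for Cxcr2, 0.532 for Cxcl3, 0.644 for Cxcl2, 0.741 for Chil3 and 0.650 for Dmkn, each at the low end. In vehicle tumour C_375_S31 the gap was 0.656 for the score of cell cycle genes and 0.629 for Cd209a, each at the low end.

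The T cell marker score was higher in triple than in dual tumours by 1.17 (exact permutation p = 0.0123, adjusted over 32 lists 0.0682). A lower share of tumour cells would raise the markers of every host cell type alike. The T cell score minus the neutrophil score differed by 1.06 (two-sided exact permutation p = 0.0042), so these 2 lists did not rise alike. Score differences of triple minus dual were 1.01 for macrophage, 0.94 for natural killer, 0.73 for endothelial and 0.64 for fibroblast lists. They were 0.11 for neutrophil, -0.03 for dendritic cell and -0.52 for erythroid lists. With lists on both sides, 1 comparison list cannot decide whether a lower share of tumour cells contributed. The lowest median T cell log2 fold change over 3 other scalings was 0.99 against 1.17, which argues against scaling. With the muscle score as a covariate the T cell score difference fell to 0.514 (exact permutation p = 0.0724), and is no longer past the threshold because the difference itself shrank, so more host tissue in the tumour piece may account for much of it. The muscle list score and the T cell score correlated within the triple group (r = 0.876, permutation p = 0.00434, adjusted over 3 groups 0.013). Their rho was 0.905 (permutation p = 0.00456), and r was 0.855 without tumours T_331_S44 and T_360_S46. In dual tumours r was 0.376 and rho 0.310 (permutation p = 0.354 and 0.462), and in vehicle tumours 0.510 and 0.333 (permutation p = 0.199 and 0.428). The relation to the T cell score was computed for the muscle list alone. Among triple tumours, T cell scores were lowest in T_331_S44 (-1.03) and highest in T_352_S48 (1.98). So were adipocyte scores (-1.31 and 2.01) and macrophage scores (-0.95 and 2.50). The relation is thus not shown to be particular to muscle. An effect of C5aR1 blockade on T cells stays open as well, since a response that also changes how much host tissue a small tumour piece holds would give the same relation and was not tested.

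Neutrophil markers were higher in both treated groups than in vehicle. If blood of unchanged composition carried in the tumour piece were the cause, erythroid markers would rise with them. The mean log2 value of neutrophil minus erythroid markers exceeded that of vehicle by 2.76 in the treated group with the lower difference and by 3.47 in the other (exact permutation p = 0.0002 in both, the smallest that 8 against 8 tumours can give). This argues against carried blood with an unchanged ratio of neutrophil to erythroid transcripts. That ratio in the blood was not measured, so the test cannot weigh blood in which it changed. Poly I:C injected into the tumour remains an open candidate explanation, which the design does not separate from PD-1 blockade.

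Without the 5 triple tumours with the most muscle reads, limma called 2 genes between triple and dual, with 1794 genes at an unadjusted p under 0.05. The number of calls was the lowest over all 56 choices of 5 triple tumours to leave out, whose median was 2339 and highest 9082, and 3 choices gave it (5.36%). Most choices thus gave far more calls, though 17 of the 56 gave under 100. The share of 5.36% lies just above a bound of 5% set after the results were seen. Muscle content and the lower number of tumours therefore cannot be told apart as the cause by this test. The median size of the fold changes of the 4007 genes fell from 0.55 to 0.24. Leaving out the 2 tumours with over 0.2% muscle reads gave 850 calls, the lowest of 28 choices of 2, whose median was 3167.5.

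Of 100 splits of the tumours of each comparison, the real one included, 1 gave as many calls as dual against vehicle (5760, highest other 3129). Likewise 1 gave as many as triple against vehicle (8560, highest other 3104). In both this was the real split, and 1 in 100 is the smallest share the test can give. Chance is thus unlikely for both, but 100 splits cannot exclude it. For triple against dual 2 of 100 splits gave as many as 4007. The other split called 5385 genes, more than the real one, so the test cannot exclude chance for this comparison. A structure among these tumours besides the group remains possible and was not tested.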

How the results depend on the processing

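The adipocyte covariate, precision weights, median-of-ratios scaling and the fits without muscle-rich triple tumours were chosen after seeing the data. Counts as higher and lower: in dual against vehicle, tumour weights gave 4436 and 4775, an adjusted p under 0.01 gave 1769 and 1685, and a 2-fold minimum 738 and 727. In triple against vehicle, the muscle covariate gave 1893 and 1862, the adipocyte covariate 2798 and 2616, leaving out the 5 muscle-rich triple tumours 2853 and 2848, an adjusted p under 0.01 gave 2962 and 2807, and a 2-fold minimum 2105 and 984. In triple against dual, the muscle covariate gave 6 and 3, leaving out those 5 tumours 2 and 0, leaving out the 2 above 0.2% muscle reads 454 and 396, the adipocyte covariate 914 and 659, the fit on 2 groups 806 and 568, the exact Wilcoxon test 3.6e+02 (rounded) and 433 of 789, median centring 1724 and 2976, an adjusted p under 0.01 440 and 330, and a 2-fold minimum 898 and 112. Quantile normalization moved the median of all genes to -0.11 in triple against vehicle. Leaving out each tumour in turn gave 1311 (without triple tumour T_352_S48) to 3598 higher (without T_331_S44) and 1081 (without T_353_S45) to 3075 lower (without T_331_S44) in triple against dual, and stayed within 1.5 times for the other comparisons. The number of lists called was 0 in each comparison with an estimated correlation, 9 in dual against vehicle and 9 in triple against dual with fry, and 3 in triple against dual with the score permutation.

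The direction of camera's test changed for these lists that were called in either fit, given with their medians: without the 5 tumours, macrophage markers (0.043, where the test went down) in triple against vehicle, and in triple against dual type I interferon (-0.12), checkpoint (-0.025), neutrophil (-0.26), mast cell and eosinophil (-0.73), cell cycle (0.24), fibroblast (0.071, where the test went down) and muscle markers (-0.12). With the muscle covariate it changed for adipocyte markers in triple against vehicle (-0.15) and type I interferon genes in triple against dual (-0.028). Lists not called in triple against dual that gained a lower call with the muscle covariate and without the 5 tumours, given in that order, were regulatory T cell (median -0.49 and -0.50, adjusted p = 0.0139 and 0.000528), inflammatory (-0.24 and -0.55, adjusted p = 0.037 and 5.8e-07) and erythroid markers (-1.17 and -1.70, adjusted p = 0.0208 and 6.19e-05). Dendritic cell markers gained a lower call without the 5 tumours alone (median 0.11 to -0.23, adjusted p = 0.00147), as epithelial and mesenchymal genes gained a higher one (0.09, adjusted p = 0.0386). In triple against vehicle cell cycle genes gained a higher call in both fits (adjusted p = 0.0416 and 2.13e-06), mast cell and eosinophil markers a lower one with the covariate (adjusted p = 0.0402) and erythroid markers a lower one without the 5 (adjusted p = 0.0193). Medians of further lists changed sign where neither fit called the list or the test kept its direction. Stricter thresholds call fewer genes by construction and fits without tumours hold fewer samples. For the rest the cause was not tested. The fit without the 5 tumours held 3 triple tumours, T_331_S44, T_360_S46 and T_363_S41. Their regulatory T cell scores were -0.94, -0.10 and -0.45, and their inflammatory scores -0.57, 0.18 and 0.13. The list calls of both muscle fits used camera with the preset correlation of 0.01. Camera with an estimated correlation was not run on them, and called 0 lists in the main fits. Of the 101 values of genes named by the rule fixed in advance, 28 lost their call with the muscle covariate and 27 without the 5 tumours. With the exact Wilcoxon test 19 lost it, all in triple against dual, where limma had called 25. Without the 2 tumours above 0.2% muscle reads 12 lost it, at an adjusted p under 0.01 11, and with median centring 0. None that was called in either run changed direction in any alternative run. Pseudocounts had been planned only for linear values and count models only for raw counts, and neither was run. Low read counts limit Hc, for which no difference was detectable at this depth.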

Other observations

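The 4 added gene lists, the genes named from them and the genes named from the covariate fit were chosen after the data were seen, so their p describes these tumours only.

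Genes of oxidative stress defence and iron handling, such as the NRF2 target Nqo1 and the ferritin chains, rose in 25 of 25 members in dual against vehicle (median log2 fold change 1.13; camera adjusted p = 4.35e-28; adjusted p = 0.0021 with an estimated correlation) and in 24 of 25 in triple against vehicle (median 1.06; camera adjusted p = 7.58e-19; adjusted p = 0.0131 with an estimated correlation). Sterol biosynthesis genes fell in 20 and rose in 1 of 24 in triple against vehicle (median -0.76; camera adjusted p = 5.41e-05; adjusted p = 0.269 with an estimated correlation) and fell in 10 and rose in 1 against dual (median -0.61; camera adjusted p = 6.06e-06; adjusted p = 0.414 with an estimated correlation; 0.106 in the permutation test of the score). With the muscle covariate the sterol medians were -0.26 and -0.28 (camera adjusted p = 0.0427 and 0.00111), and without the 5 muscle-rich triple tumours neither was called (0.162 and 0.858). Genes of the circadian clock and its output rose in 10 and fell in 1 of 18 in triple against vehicle (camera adjusted p = 0.00165; adjusted p = 0.14 with an estimated correlation) and rose in 5 against dual (camera adjusted p = 0.0134; adjusted p = 0.414 with an estimated correlation); the hour at which tumours were taken is not given in the sources used here. Markers of resident-type macrophages and type 2 dendritic cells fell in 10 of 18 in dual against vehicle (median -1.10; camera adjusted p = 7.21e-06; adjusted p = 0.174 with an estimated correlation) and fell in 10 and rose in 2 in triple against vehicle (median -1.54; camera adjusted p = 0.000185; adjusted p = 0.206 with an estimated correlation). The other calls of these 4 lists stayed in both muscle fits, and the resident-type list, not called in triple against dual (camera adjusted p = 0.774), was called lower there without the 5 tumours (median -0.54; adjusted p = 0.00158).

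Among the lists fixed in advance, monocyte markers rose in 10 and fell in 5 of 18 in dual against vehicle, with 11 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0303; adjusted p = 0.75 with an estimated correlation; 0.11 with the muscle covariate) and rose in 7 in triple against dual, with 7 adjusted over the list alone (camera adjusted p = 0.00105; adjusted p = 0.624 with an estimated correlation). Fibroblast and extracellular matrix genes rose in 5 and fell in 1 of 30 in triple against dual, with 6 higher and 1 lower adjusted over the list alone (median 0.76; camera adjusted p = 0.000481; adjusted p = 0.658 with an estimated correlation). That call was lost with the muscle covariate (median 0.32, adjusted p = 0.0664) and without the 5 muscle-rich triple tumours (adjusted p = 0.71), as was the monocyte call in triple against dual without those 5 (adjusted p = 0.519). Checkpoint and exhaustion genes rose in 12 and fell in 2 of 20 in triple against vehicle, with 12 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000178; adjusted p = 0.345 with an estimated correlation), a call lost with the muscle covariate (adjusted p = 0.0537) and without those 5 tumours (adjusted p = 0.148). Cell cycle genes rose in 9 of 36 in dual against vehicle, with 9 adjusted over the list alone (camera adjusted p = 0.00749; adjusted p = 0.755 with an estimated correlation; 0.0551 without vehicle tumour C_375_S31).

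With the muscle score as a covariate, limma called 9 genes between triple and dual. Serpinb10 (2.67), Ppl (2.38), Crybb1 (2.79), Inpp5j (1.70) and Prxl2a (1.27) were among those higher. The chemokine gene Ccl22 (-2.58), the lectin gene Mgl2 (-3.23) and Car3 (-0.77) were lower. The lowest adjusted p was 0.00203, for Ppl, and the highest 0.0488, for Crybb1.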
